A study of Homo sapiens with 2 samples.

How the data were processed

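RNA was measured by poly(A)-selected RNA sequencing in A2780 cells, an established human ovarian cancer cell line. There were 2 libraries, 1 labelled shControl and 1 labelled shJAM3, the second from cells in which JAM3 was targeted for stable knockdown. The labels name the first a wild-type genotype, and the design text calls it an empty-vector control. That text speaks of siRNA while the titles carry the prefix sh. The construct's sequence is not given in the sources used here. Per the labels' protocols, mRNA was captured on oligo-dT beads, fragmented, copied with random hexamers, size-selected and amplified by PCR. The protocol as given describes no step that marks the strand, and no molecular identifiers.

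The authors deposited 1 table of FPKM (fragments per kilobase of gene length, scaled to the library size) with 58735 genes, their symbols, coordinates, lengths and biotypes. The submitters' processing notes name fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0, edgeR 3.22.5, GATK 4.1.1.0, STAR and STAR-Fusion, with no role or order. The genome build and annotation are not given in the labels. All 58735 deposited gene identifiers, coordinates and symbols were found unchanged in GENCODE release 29 (GRCh38). Each deposited gene length equalled the union of that gene's annotated exons there, so coordinates are given in GRCh38.

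Fragment numbers were recovered from the values. Each deposited FPKM multiplied by its gene length was a whole multiple of 1 step per library, for 100% of the values above 0 in both libraries (tolerance 0.001 fragments). The recovered totals were 15570262 fragments for shControl and 16455079 for shJAM3. The library sizes implied by the FPKM were 15361731 and 16678451, which are 0.987 and 1.014 times these totals. The product of the 2 factors was 1, so the deposited FPKM carry a scaling between the libraries in addition to the total. The method of that scaling is not given in the sources used here.

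Rows sharing a symbol were reduced to the one with the highest mean FPKM, which left out 1566 rows and kept 57169. The main measure was the log2 ratio of shJAM3 to shControl on the scale log2(FPKM + 1), which understates differences of genes near or below 1 FPKM. Genes with a mean of at least 1 FPKM over both libraries were taken as measured. With 1 library per group no test of the conditions was possible, so no p-value is given. A fixed rule of size was used in its place, a log2 ratio of at least 1 in either direction. Each ratio of FPKM without the added 1 carries an exact 95% interval from the recovered fragments (conditional binomial). These intervals compare the 2 libraries and cover counting error only. They leave out the spread between cultures, and PCR copies make them too narrow.

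Lists of genes were written down before the data were examined, 46 in all with 1126 distinct genes, of which 79 stood in more than 1 list. JAM3 itself was left out of the lists. A list's median log2 ratio was placed among 10000 random lists of the same size, drawn with replacement from protein-coding genes in the same 20 bins of mean expression. A list was said to lie outside the random range below percentile 2.5 or above 97.5. This describes these 2 libraries and is no test of the conditions. By construction about 2.1 of 42 random lists would lie outside the range. Members of a real list can move together for any reason, technical reasons included, so that number is no error rate. Lists with fewer than 5 measured members were given as values. The rule for naming genes was also fixed in advance: JAM3, the 12 highest and 12 lowest protein-coding genes with a mean of at least 5 FPKM, F11R, JAM2, ESAM, AKT1, AKT2, PIK3CA, PIK3R1 and other genes, and up to 4 members of each described list with the largest absolute log2 ratio. Near-identical copies of a named gene and 1 overlapping neighbour were added afterwards. Some genes that this rule takes are not reported here.

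The alternatives fixed in advance were a pseudocount of 0.1 FPKM, 2 other scalings, other filters on low values, protein-coding genes only, the counting interval as an added condition, another background, the list mean, and matching on gene length. Matching or centring on transcript GC content and a minimum of 50 fragments were chosen after seeing the data. GC content came from GENCODE 29 transcript sequences and was available for 10496 of 10499 measured protein-coding genes. Centring used 20 GC bins. Matching used 10 bins of mean expression, each split into 10 GC bins. GC centring of the ratio without the added 1 was also chosen after seeing the data. It was used for PIK3CA, PIK3R1, COL1A1, ENG and UPK3B only. The added 1 draws low genes such as PIK3R1 and UPK3B towards 0 before centring. COL1A1 and ENG are not low, and for them the added 1 mattered little. The size rule was tested on simulated counts, 58735 genes with the mean counts and library sizes of this comparison and counting error only. The size rule found 100% of 100 genes made 3-fold higher and 100% of 100 made 3-fold lower. These genes were drawn from protein-coding genes with a mean of at least 5 FPKM. A 3-fold difference at that level lies past the rule even with the added 1. Recovery of changed genes with lower values was not tested. Of 12073 unchanged simulated genes 46 passed it, none of them protein-coding (0). The placing of lists was tested on simulated log2 ratios of the measured protein-coding genes, drawn independently for each gene. Random null lists of 25 genes fell outside the range in 4.5% of 200 cases, and lists shifted by 0.3 were called in 94.5%. Smaller lists were not simulated, and that share does not hold for them. For the 6 measured neuronal genes the random range ran from -0.39 to 0.35, so a median of 0.3 would lie within it. A trend was also simulated from the GC values that the matching uses. GC-rich null lists then fell outside in 81% of cases when matched on expression and in 4.5% when matched on expression and GC. That checks the matching for such a trend only, not for GC effects that gene-level values miss. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Overlapping exons were looked up for JAM3, the ranked genes and the other genes fixed by name, not for the members of the lists. Sequence variants and gene fusions were not analysed here.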

Results

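The transcriptomes of A2780 ovarian cancer cells labelled shControl and shJAM3 were compared, with 1 library in each group. JAM3 encodes junctional adhesion molecule C, a cell-surface protein of cell-cell contacts. The series title places the comparison in the context of JAM3 loss and the PI3K/AKT pathway. The shControl library held 15570262 fragments assigned to genes and detected 21954 genes, and the shJAM3 library held 16455079 fragments and detected 22401 genes. Protein-coding genes took 97.8% of the fragments in shControl and 97.4% in shJAM3. Across the 12214 measured genes, log2(FPKM + 1) correlated between the libraries with r = 0.96, across genes that are not independent replicates. As no group had a second library, every difference below is a difference between these libraries and has no replicate check. Bracketed intervals are 95% intervals for counting error only. They excluded 1 for 7485 of 10499 measured protein-coding genes, so an interval that excludes 1 was common.

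JAM3 was barely detected in either library. It had 18 fragments in shControl (0.215 FPKM) and 14 in shJAM3 (0.154 FPKM), and 12469 of 19932 protein-coding genes had a higher mean FPKM. The ratio of shJAM3 to shControl was 0.716 (0.330 to 1.52), so a difference in JAM3 was not detectable at this depth. The study's design text states a reduction of more than 70%, which would leave a ratio below 0.3. The lower bound of the interval, 0.330, lay slightly above that. JAM3 (ENSG00000166086) lies on chromosome 11 at 134068925 to 134152001 on the plus strand of GRCh38. At its 3' end it shares 465 bases, 8.53% of its exon bases, with NCAPD3 on the opposite strand, a condensin subunit gene with 27.5 FPKM in shControl and 36.0 in shJAM3. Without strand information, fragments from that stretch cannot be assigned to either gene. Of the related adhesion molecules, F11R (JAM-A) was at 8.51 FPKM in shControl and 4.83 in shJAM3, a ratio of 0.568 (0.501 to 0.643). A second annotated gene covers 36.6% of the F11R exon bases. ESAM had a ratio of 0.734 (0.662 to 0.814). JAM2 had no fragment in either library. With 3 fragments taken as the limit for a gene with none, that limit was 0.0329 FPKM in shControl and 0.0303 in shJAM3. It allows for counting error only.

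Most genes differed little between the libraries, and 76.6% of measured genes lay within 0.5 of 0 on the log2 scale. By the rule of size, 159 genes were at least 2-fold higher in shJAM3 and 257 at least 2-fold lower. Of the protein-coding genes, 41 were higher and 148 lower. The other 227 genes past the rule included 97 small RNA genes. The log2 ratio followed the GC content of the transcripts. With protein-coding genes in 10 equal groups by GC, the median was 0.24 in the group with the lowest GC and lower in each successive group, down to -0.45 in the group with the highest, with r = -0.51 across 10496 genes. Protein-coding genes past the rule had a median GC of 42.9% where higher and 61.2% where lower, against 49.9% for all measured. After each gene was centred on its GC bin, 33 protein-coding genes were higher and 71 lower, which moved the higher share from 21.7% to 31.7%. GC centring moved the log2 ratio of 113 named genes beyond their counting error, so ratios of single genes below carry the GC trend. FASN, for example, went from -0.76 to -0.26 and COL7A1 from -0.94 to -0.44. Percentiles of gene lists are given both with matching on expression and with matching on expression and GC.

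**Figure D1:**
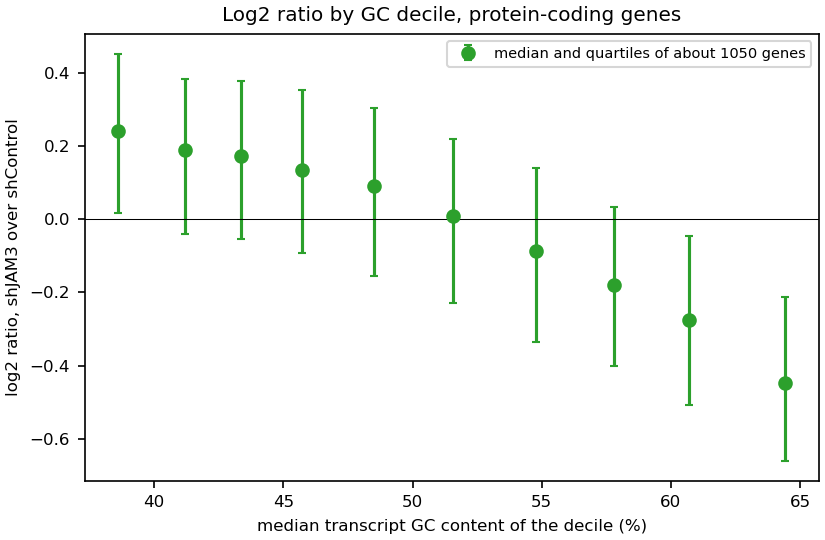
Median log2 ratio of shJAM3 to shControl (y axis, FPKM + 1) against the median transcript GC content in percent (x axis) of 10 equal groups of measured protein-coding genes; bars span the quartiles of the genes. The median is 0.24 in the group with the lowest GC and -0.45 in the group with the highest.

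The protein-coding genes with the highest ratios included several enzymes, transporters and RNA-processing factors. SPINK5, a serine protease inhibitor on chromosome 5 (148025683 to 148137289), was at 16.1 FPKM in shControl and 72.5 in shJAM3, a ratio of 4.51 (4.23 to 4.82). RGS2, a regulator of G protein signalling, was at 20.8 and 76.6 FPKM, a ratio of 3.69 (3.38 to 4.02). PDK4, a kinase that inhibits pyruvate dehydrogenase, had a ratio of 3.41 (3.04 to 3.83). RRM2, the small subunit of ribonucleotide reductase, had a ratio of 3.66 (3.16 to 4.24), with 20.2% of its exon bases shared with another annotated gene. RAD51AP1, a homologous recombination factor, had a ratio of 2.76, and the splicing-related genes ZRANB2 and U2SURP had ratios of 3.27 and 2.90. Another annotated gene shares 8.39% of the ZRANB2 exon bases, and PAQR9-AS1 and AC026304.1 share 6.93% and 2.70% of the U2SURP exon bases. The phosphodiesterase PDE10A was 3.38-fold higher, the lipoprotein receptor OLR1 2.90-fold, the zinc transporter SLC39A10 2.60-fold and the monocarboxylate transporter family member SLC16A6 2.56-fold. SMN1 headed the ranking at 2.82 and 21.3 FPKM, but its near-identical copy SMN2 makes its value uncertain.

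The protein-coding genes with the lowest ratios included histones, transcription factors and secreted or membrane proteins. C11orf86, on chromosome 11 (66975277 to 66977004), was at 140.2 FPKM in shControl and 32.4 in shJAM3, a ratio of 0.231 (0.211 to 0.252). The zinc finger gene GLIS2 had a ratio of 0.219 (0.197 to 0.243), with 24.5% of its exon bases under an antisense gene. CLIP2, which binds microtubules, had a ratio of 0.244 (0.230 to 0.259). TNFSF9, the ligand of the costimulatory receptor 4-1BB, was at 99.7 and 30.6 FPKM, a ratio of 0.307 (0.284 to 0.332). SLC6A12, a betaine and GABA transporter, and SECTM1 both had ratios of 0.246, and ZNF467 had a ratio of 0.254. The aldo-keto reductase AKR1C3 had a ratio of 0.304 (0.276 to 0.334). The histone genes HIST1H3B and HIST1H3H had ratios of 0.253 and 0.283, and H3 genes form a family of near-identical copies. HIST2H2AA4, with 187 and 5 fragments, and EIF3CL, with 706 and 60 fragments, also have near-identical copies and are uncertain. All 24 ranked genes were also past the 2-fold rule after GC centring.

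**Figure D2:**
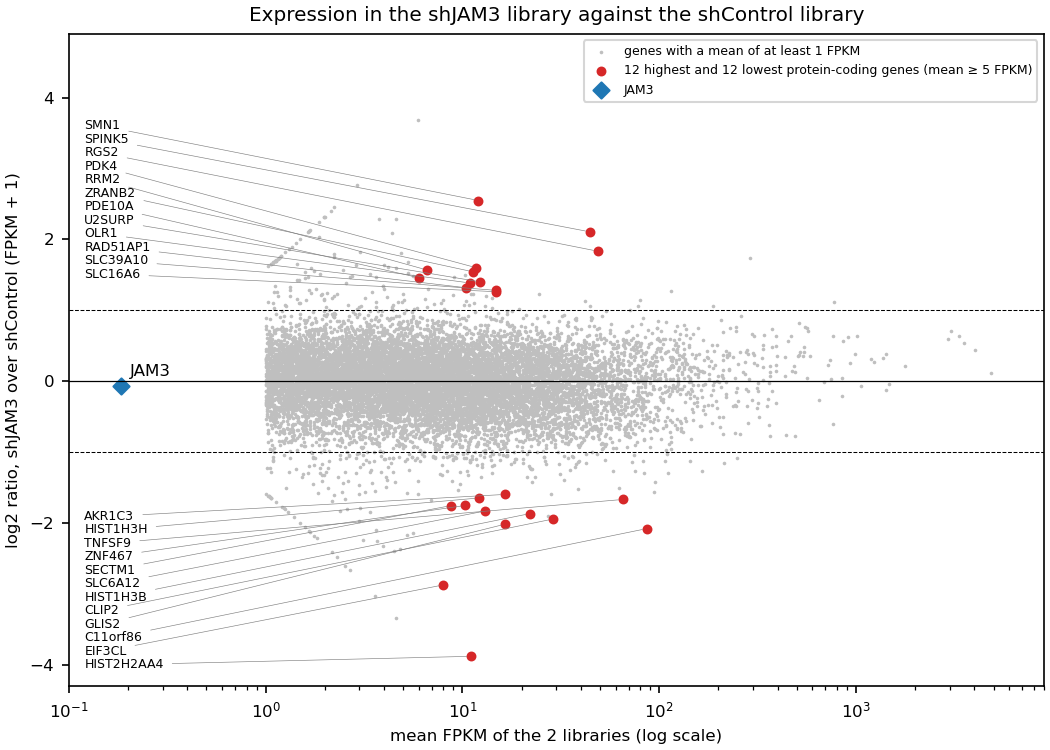
Log2 ratio of shJAM3 to shControl (y axis, FPKM + 1) against the mean FPKM of both libraries (x axis, log scale). Grey points are genes with a mean of at least 1 FPKM, red points the 12 highest and 12 lowest protein-coding genes with a mean of at least 5 FPKM. The blue diamond is JAM3, whose log2 ratio is -0.07. The added 1 draws that value towards 0, as JAM3 lies at 0.215 and 0.154 FPKM. Dashed lines mark the 2-fold rule.

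Tight junction, integrin and extracellular matrix genes were on the lower side in shJAM3. Of 19 measured tight junction and JAM family genes 13 were lower, with a median log2 ratio of -0.35, at percentile 0.11 of random lists and 0.07 with GC matching. The median of the GC-centred ratios was -0.16. CLDN4, a claudin, was at 33.2 FPKM in shControl and 11.7 in shJAM3 (ratio 0.354), the zonula occludens gene TJP3 had a ratio of 0.477, and the polarity gene PARD6B a ratio of 0.488. With no filter on low values this list lay at percentile 10.8, within the range. Of 25 matrix genes 22 were lower, with a median of -0.36 (percentiles 0.11 and 0.72). They included the crosslinking enzyme LOXL2 (ratio 0.450), COL7A1 (0.515), NID2 (0.496) and COL6A1 (0.564). Of 20 integrin and focal adhesion genes 15 were lower, with a median of -0.34 (percentiles 0.78 and 0.40), among them the adaptor BCAR1 (0.516), ITGB4 (0.569), TNS3 (0.598) and VCL (0.639).

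Adherens junction and desmosome genes split evenly, 8 higher and 8 lower, with a median of -0.10 at percentile 25.6 (13.3 with GC matching). The members furthest from 0 were JUP at a ratio of 0.634, VCL, NECTIN2 at 0.650 and PKP3 at 0.685. GC centring took the log2 ratio of JUP from -0.65 to -0.34, of NECTIN2 from -0.59 to -0.28 and of PKP3 from -0.53 to -0.02. Of 15 mesenchymal genes 10 were lower, with a median of -0.30 at percentile 2.57, just within the range, and 0.64 with GC matching. The transcription factors TWIST2 (0.451), FOXC2 (0.577) and TWIST1 (0.549) were among the most distant. Epithelial genes split into 7 higher and 7 lower, with a median of -0.04 (percentiles 43.6 and 87.6). The median was 0.07 after GC centring and -0.31 among genes with a mean of at least 5 FPKM (percentile 4.17), and the list mean was -0.24 (percentile 4.11), both percentiles within the range. CLDN4, ELF3 (0.449), KRT7 (0.666) and CLDN7 (0.658) were the most distant, all lower. Matrix proteases and their inhibitors had a median of -0.10 (percentiles 24.8 and 19.9), or 0.04 after GC centring, with TIMP3 (0.565), TIMP2 (0.620) and ADAMTS1 (0.690) lower.

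Transcripts of PI3K/AKT pathway components did not stand apart from random genes. Of 34 measured components 14 were higher and 20 lower, none past the 2-fold rule, with a median of -0.13 at percentile 6.50 (8.70 with GC matching). AKT1 was at 19.2 FPKM in shControl and 14.6 in shJAM3, a ratio of 0.758 (0.720 to 0.797). AKT2 had a ratio of 0.808 (0.763 to 0.856). GC centring took the log2 ratio of AKT1 from -0.38 to -0.15 and that of AKT2 from -0.28 to -0.07. PIK3CA, the catalytic subunit p110-alpha, had a ratio of 1.07 (0.912 to 1.25), with 35.8% of its exon bases shared with a gene on the other strand. PIK3R1 had 10 and 24 fragments, a ratio of 2.21 (1.02 to 5.18). With GC centring of the ratio without the added 1, the log2 value of PIK3CA was -0.24 (-0.47 to -0.01), of the opposite sign, and that of PIK3R1 was 0.92 (-0.20 to 2.14), an interval that includes 0. The members furthest from 0 were PIK3C2A (1.93), INPPL1 (0.612), PHLPP1 (0.581) and the mTOR inhibitor DEPTOR (1.75). These are transcript levels, and pathway activity was not measured here.

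Growth factor receptors and ligands that signal through PI3K were mostly lower. Of 21 measured 17 were lower, with a median of -0.33 at percentile 0.30, and at 2.52 with GC matching, just inside the range. VEGFA was at 22.1 and 10.2 FPKM (ratio 0.461), FGF2 had a ratio of 0.596 and EPHA2 of 0.619, while the receptor MET was at 1.68. FOXO targets, which AKT signalling keeps low, went both ways, 9 higher and 12 lower, with a median of -0.10 (percentiles 20.6 and 4.97). The median was -0.21 after GC centring, and the list mean was -0.01 (percentile 59.4). PDK4, TXNIP (2.39) and MXI1 (2.07) were higher, and PINK1 (0.456) was lower.

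Genes of the translation machinery were on the higher side in shJAM3. Of 52 cytosolic ribosomal protein genes 49 were higher, 47 of them beyond counting error, with a median of 0.37, above all 10000 random lists with either matching. Among all measured protein-coding genes 7485 of 10499 differed beyond counting error in either direction. RPL32 was at 97.6 FPKM in shControl and 169 in shJAM3 (ratio 1.73), and RPS27, RPL6 and RPL27 had ratios of 1.71, 1.68 and 1.68. Many ribosomal protein genes have processed pseudogenes that can share their fragments. Of 31 MYC targets and ribosome biogenesis genes 24 were higher, with a median of 0.30 (percentiles 99.99 and 100). They included PA2G4 (1.90), NOLC1 (1.81) and NOP56 (1.78), while PPAN was lower (0.512).

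Replication genes were also mostly higher. Of 35 G1/S and DNA replication genes 24 were higher, with a median of 0.23 (percentiles 99.8 and 99.3). Besides RRM2, these included CCNE1, which encodes cyclin E1 (8.86 and 17.6 FPKM, ratio 1.98), GINS3 (2.01) and POLE2 (1.96). Of 34 mitotic genes 25 were higher, with a median of 0.23 at percentile 99.9, but at 90.3 with GC matching, within the range. MKI67, a proliferation marker, had a ratio of 1.75, PTTG1 of 1.61, CENPE of 2.35 and CDC25B of 0.621. CDK inhibitors and senescence genes were lower in 10 of 16 cases, with a median of -0.33 (percentiles 0.81 and 0.17). CDKN2B, which encodes p15, had a ratio of 0.428, IL6 of 0.463, CDKN2D of 0.542 and CDKN2A of 0.632. Among genes with a mean of at least 5 FPKM this list lay at percentile 3.92, within the range.

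Replication-dependent histone genes went the other way from the replication genes. Of 20 measured 15 were lower, 5 of them past the 2-fold rule. Counting error was exceeded by 10, all below 1, against 7485 of 10499 measured protein-coding genes in either direction. The median was -0.49, below all 10000 random lists with either matching. Besides HIST1H3B and HIST1H3H, the most distant were HIST1H1C (139.6 and 51.3 FPKM, ratio 0.367) and HIST1H4H (0.334). Most mRNAs of these genes carry no poly(A) tail, so in poly(A)-selected libraries they are captured only in part.

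Genes of mitochondrial respiration were higher and genes of sterol synthesis lower. Of 39 nuclear-encoded oxidative phosphorylation genes 31 were higher, with a median of 0.25 (percentiles 99.98 and 99.2), among them ATP5F1C (1.74), ATP5MC1 (1.54), NDUFA4 (1.54) and COX6B1 (79.8 FPKM in shControl and 119.8 in shJAM3). Of the 13 mitochondrially encoded mRNAs 12 were higher, with a median of 0.38 at percentile 99.5, but at 80.3 with GC matching. MT-CO3, MT-ATP6, MT-CYB and MT-ND4 had ratios of 1.64, 1.55, 1.55 and 1.51. All mitochondrial genes together took 2.58% of fragments in shControl and 3.58% in shJAM3. Of 24 cholesterol synthesis genes and SREBP2 targets 18 were lower, with a median of -0.34 (percentiles 0.38 and 0.06). INSIG1, which holds back SREBP processing, was at 107.2 and 60.1 FPKM (ratio 0.561), and the sterol reductase gene TM7SF2 had a ratio of 0.533.

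Fatty acid synthesis genes had a median of -0.07 (percentiles 29.99 and 32.6), although AGPAT2 (0.563), SREBF1 (0.570), FASN (0.588) and SCD (0.659) were lower. Their mean was -0.18 (percentile 8.69), and their median at a mean of at least 5 FPKM was -0.14 (percentile 17.7). Glycolytic genes had a median of 0.11 (percentiles 85.5 and 93.6), with PFKFB3 (0.511), HK2 (0.568) and SLC2A1 (0.590) lower and PFKM (1.49) higher. The mean of this list was -0.03, of the opposite sign to its median. Of 21 hypoxia response genes 12 were lower, with a median of -0.31 (percentiles 0.56 and 0.06). ADM, which encodes adrenomedullin, had a ratio of 0.412, VEGFA of 0.461 and PFKFB3 of 0.511, while MXI1 had a ratio of 2.07.

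Among signalling outputs, NF-kB and TGF-beta targets were on the lower side. Of 16 NF-kB targets and cytokines 11 were lower, with a median of -0.48 (percentile 0.01, and below all random lists with GC matching). NFKBIA, the inhibitor induced by NF-kB itself, was at 52.5 and 22.7 FPKM (ratio 0.432), RELB had a ratio of 0.424, IL6 of 0.463 and NFKB2 of 0.543. Of 19 TGF-beta and BMP targets 13 were lower, with a median of -0.43 (percentiles 0.06 and 0.03), among them BAMBI (0.427), NOG (0.520) and SMAD6 (0.538). Antigen presentation genes, with HLA-B (0.512), TAP1 (0.610), HLA-C (0.634) and NLRC5 (0.563) the most distant, had a median of -0.34 at percentile 1.81, and at 3.40 with GC matching, within the range. HLA genes are polymorphic and similar to one another, so their values are uncertain. WNT targets and regulators had a median of -0.26 at percentile 1.19, and at 9.76 with GC matching. LGR6, FZD7, NOTUM and WNT7B had ratios of 0.387, 0.444, 0.541 and 0.542.

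The remaining signalling lists had medians within the random range. NOTCH pathway genes were lower in 13 of 15 cases with a median of -0.25 (percentile 3.35), and HES6, NRARP, NOTCH3 and HES4 had ratios of 0.348, 0.545, 0.575 and 0.575. This list lay below the range under 4 alternatives, at percentile 1.03 with a pseudocount of 0.1 FPKM, 1.0 with no filter on low values, 0 at a mean of at least 5 FPKM (median -0.63) and 0.02 by the list mean (-0.41). With GC matching it lay at percentile 45.1, and its members had a median GC of 61.1%. Immediate-early genes had a median of -0.19 (percentiles 5.83 and 25.7, but 1.11 by the list mean, below the range), or -0.03 after GC centring. IER3 (0.405), IER5 (0.421), KLF2 (0.422) and DUSP1 (0.598) were lower. Genes that report ERK output had a median of -0.10 (percentiles 21.8 and 34.0), or -0.25 after GC centring, with IER3 and DUSP5 (0.571) lower and CCND1 (1.63) higher. YAP/TEAD targets had a median of -0.11 (percentiles 22.2 and 28.9), with GADD45A (0.518) and LATS2 (0.623) lower and TEAD4 (1.61) higher.

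**Figure D3:**
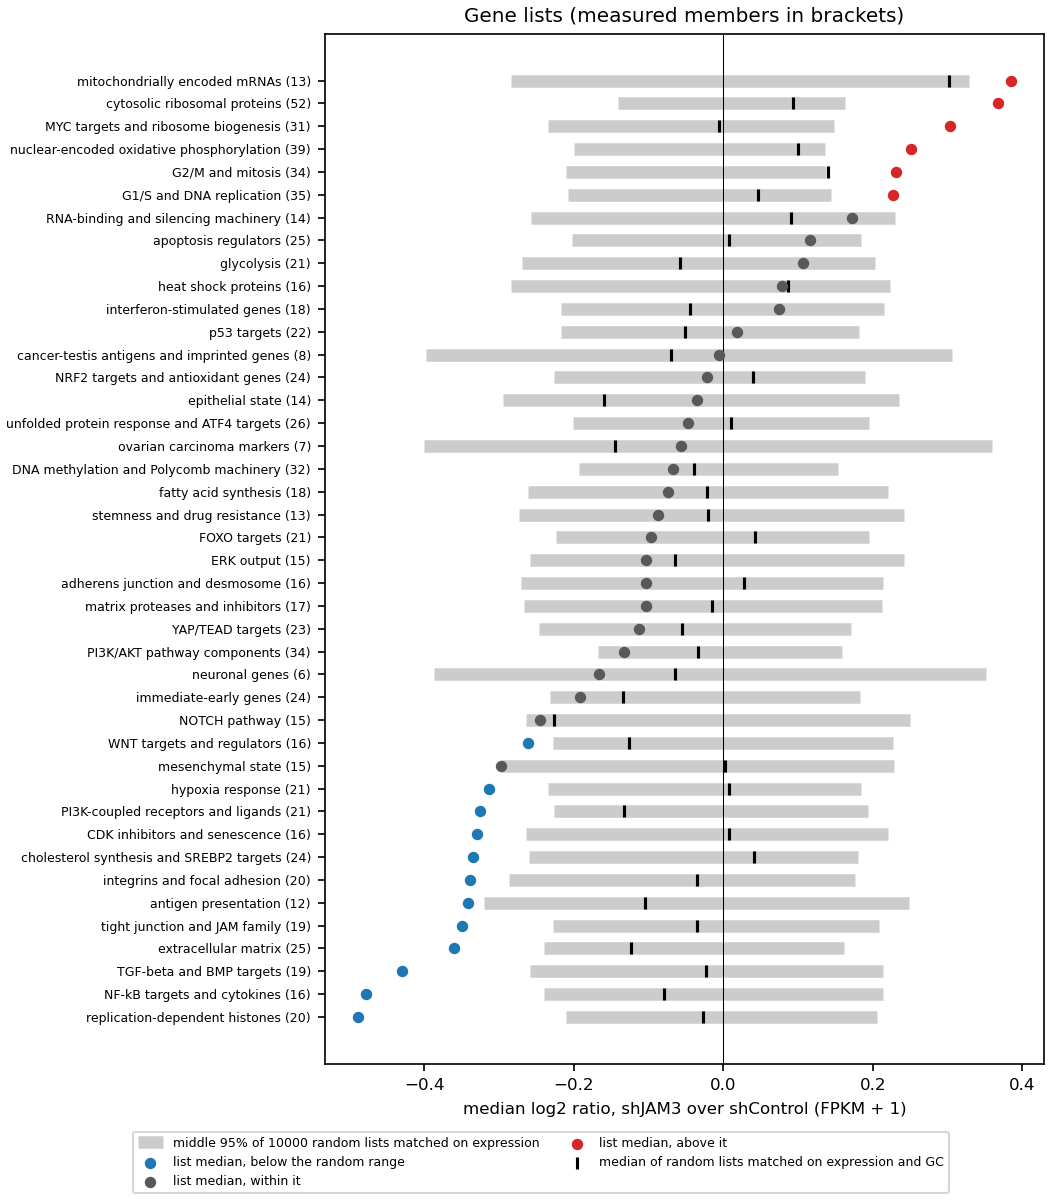
Median log2 ratio of shJAM3 to shControl (x axis, FPKM + 1) for each gene list (y axis, measured members in brackets). Points are list medians coloured by whether they lie below, within or above the grey bars, which span the middle 95% of 10000 random lists matched on expression; black ticks are the medians of random lists matched on expression and GC. Of 42 lists 12 lie below the bars and 6 above, from -0.49 for replication-dependent histones to 0.38 for mitochondrially encoded mRNAs.

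Markers of other cell types were mostly near or at 0. Of 14 fibroblast markers 3 reached a mean of 1 FPKM, namely FBLN1 (111.0 and 76.6 FPKM), PDGFRB (3.79 and 2.99) and COL1A1 (13.5 and 11.3), while COL1A2 had no fragment and COL3A1 had 13 and 2. Of 14 endothelial markers EGFL7 (89.4 and 51.2 FPKM), ENG (50.0 and 44.1) and ESAM (18.7 and 13.7) reached it, and PECAM1 had 5 and 4 fragments. Of 18 leukocyte markers CD14 reached it, with 66 and 24 fragments, and PTPRC had none. Of 11 mesothelial markers MSLN (197.5 and 126.7 FPKM) and UPK3B (1.54 and 0.924 FPKM) reached it. The measured markers were lower in shJAM3, but with GC centring of the ratio without the added 1 the log2 values of COL1A1 and ENG were above 0, at 0.11 (0.02 to 0.20) and 0.17 (0.10 to 0.25), and the interval of UPK3B included 0 (-0.77 to 0.43). COL1A2, COL3A1, PECAM1 and PTPRC were chosen for naming after their values were seen.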

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

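GC centring moved the log2 ratio of 113 named genes by more than their counting error and left 81 within it, against 40 moved on the TPM scale, 16 by median scaling and 11 by the smaller pseudocount. The counts by the rule of size changed with the treatment of low values, with the TPM scale and with the class of genes. Against 159 higher and 257 lower genes, a pseudocount of 0.1 FPKM gave 361 and 477, and the TPM scale gave 811 and 966. On the TPM scale the added 1 and the minimum mean of 1 were kept in units of TPM. That setting therefore also changed the treatment of low values. The median log2 ratio over measured genes was 0.005 in the main setting and -0.04 on the TPM scale. No filter gave 254 higher genes, a minimum mean of 5 FPKM gave 52 and 141, protein-coding genes alone 41 and 148, and a minimum of 50 fragments 75 higher genes. The other alternatives stayed within 1.5 times the main counts, GC centring with 159 and 175 among them. The share of higher genes was 38.2%, and it was 47.6% after GC centring, 26.9% at a mean of at least 5 FPKM and 21.7% among protein-coding genes. The JAM3 log2 ratio, -0.07, ranged to -0.31 with the smaller pseudocount. Both values are drawn towards 0 by the added constant, and the ratio without it was 0.716 (0.330 to 1.52). PI3K/AKT components stayed within the random range under all 7 alternatives, at percentiles from 6.60 to 19.3. Lists below the range numbered 10 to 14 and lists above 4 to 6 under the alternatives, against 12 and 6. These counts are of 42 lists, but of 41 at a mean of at least 5 FPKM and of 46 with no filter. With no filter mesothelial markers were among the 11 below (6 members, median -0.16, percentile 0.40) and the 3 other lists of cell type markers lay within. Of these mesothelial members only MSLN and UPK3B reached a mean of 1 FPKM. CALB2 had 8 and 2 fragments, and LRRN4, WT1 and KRT6A had at most 3 in either library. With GC matching 13 of the 18 lists outside the range kept their side, 5 did not (antigen presentation, WNT, PI3K-coupled receptors and ligands, mitosis, mitochondrially encoded mRNAs), and the mesenchymal list moved outside. GC centring took the list median from -0.33 to -0.17 for PI3K-coupled receptors and ligands, from 0.23 to 0.11 for mitosis, from -0.34 to -0.13 for antigen presentation and from -0.26 to -0.11 for WNT. Antigen presentation was also within the range under 4 other alternatives, at percentiles from 2.75 to 29.6, and WNT under 2, at 6.81 and 17.1. The NOTCH list lay below the range under 4 alternatives, at percentiles from 0 to 1.03, and by the list mean immediate-early genes lay at 1.11 and mesenchymal genes at 1.64. Tight junction genes lay within the range with no filter (10.8), and CDK inhibitors and senescence genes at a mean of at least 5 FPKM (3.92). Mesenchymal genes lay below the range with length matching too (2.31), but nearer the middle with no filter (median -0.10, percentile 17.8) and at a mean of at least 5 FPKM (median -0.20, percentile 15.0). Some lists within the range changed sign, glycolysis by the list mean among them. No list moved from below the random range to above it or the reverse. The cause of these changes was not tested. GC matching and centring and the minimum of 50 fragments were chosen after seeing the data. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. Depth limits JAM3, with 18 and 14 fragments.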

Other observations

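All tests of explanations in this part were chosen after the results were seen. Further gene groups lay within the range of random lists. Heat shock protein genes had a median log2 ratio of 0.08 (percentiles 77.8 with expression matching and 47.0 with GC matching), a median of -0.02 at a mean of at least 5 FPKM (percentile 49.4) and a mean of 0.16 (percentile 97.2). Among them the cytosolic chaperones HSPA8 (49.7 FPKM in shControl and 110.7 in shJAM3), HSP90AA1 (121.2 and 254.4) and HSP90AB1 (421 and 705.9) were higher while the small heat shock protein HSPB8 was lower, at a ratio of 0.409. NRF2 targets and antioxidant genes had a median of -0.02 (percentiles 44.8 and 23.1), or 0.07 at a mean of at least 5 FPKM (percentile 75.9), and a mean of -0.15, with AKR1C3 (0.304), AKR1C1 (0.225) and SRXN1 (0.367) lower and the cystine transporter SLC7A11 (2.24) higher. The AKR1C genes are close paralogs. Unfolded protein response and ATF4 targets had a median of -0.05 (percentiles 32.0 and 26.9), or 0.05 after GC centring, with CEBPB (0.469), TRIB3 (0.536) and PPP1R15A (0.603) lower and SLC7A11 (2.24) higher. DNA methylation and Polycomb genes had a median of -0.07 (percentiles 28.0 and 36.3), with the de novo methyltransferase DNMT3A at 2.92 and 1.12 FPKM (ratio 0.384), TET3 at 0.606 and MBD4 at 1.65. RNA-binding and silencing genes had a median of 0.17 (percentiles 92.3 and 77.0), with PRKRA (1.69) and DROSHA (1.42) higher and AGO2 (0.705) and AGO4 (0.636) lower.

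The p53 targets had a median of 0.02 (percentiles 62.1 and 78.8), with GDF15 (0.561), PHLDA3 (0.560), BBC3 (0.560) and CDKN1A (0.705) lower, and their mean was -0.08. Apoptosis regulators had a median of 0.12 (percentiles 89.1 and 88.7), with CASP6 (2.20), CYCS (1.57) and CASP8 (1.74) higher and BBC3 (0.560) lower. Interferon-stimulated genes had a median of 0.07 (percentiles 72.5 and 89.5), with IFI6 (0.573) and IRF7 (0.595) lower and IFIT5 (1.49) and IFITM2 (1.31) higher. Of 22 ovarian carcinoma markers 7 were measured, with a median of -0.06 (percentiles 35.7 and 70.9) and a mean of -0.32 (percentile 3.56, within the range). CLDN4 had a ratio of 0.354, FOLR1 was at 845 and 1012 FPKM, MSLN at 197.5 and 126.7, and SOX17 at 2.78 and 2.00. PAX8, chosen after its values were seen, had 127 and 65 fragments. Stemness and drug resistance genes had a median of -0.09 (percentiles 26.7 and 25.2), with ABCC3 at 0.598. Cancer-testis and imprinted genes had a median of -0.01 (percentiles 53.3 and 68.4) and a mean of 0.08, with MEST at 1.66 and CDKN1C at 0.657. Neuronal genes had a median of -0.17 (percentiles 17.8 and 26.8), with SNAP25 at 1.30 and INA at 0.829.

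The log2 ratio was lower at higher GC content, and a candidate explanation is that GC-rich fragments were recovered less well in the shJAM3 library. Antisense and lincRNA genes whose gene bodies overlap no protein-coding gene on either strand had a slope of -0.22 per 10 percentage points of GC (bootstrap 95% interval over genes -0.32 to -0.12, 300 genes), below 0 as that explanation requires, beside -0.31 for protein-coding genes (-0.32 to -0.30). A regulatory difference between the cells that follows GC content is not excluded, and with 1 library per group it was not tested. Matching on gene-level GC content did not remove all of the list differences. Of 18 lists outside the random range 13 stayed outside when random lists were matched on GC. The matching used the GC content of all annotated transcripts of a gene together, in 10 bins, so a remaining GC effect is not excluded. What accounts for those 13 stays open. A difference brought about by the JAM3 construct is among the open explanations and was not tested, since each group holds 1 library.

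No reduction of JAM3 was detectable in shJAM3, with a ratio of 0.716 whose interval includes 1. The lower bound of the ratio, 0.330, lay slightly above the 0.3 that the stated reduction would leave at most. That margin is small, PCR copies make the interval too narrow, and the spread between cultures is not in it. A reduction to below 0.3 of control is therefore not excluded. An exchange of the 2 libraries cannot be told apart from the labelled order by JAM3 itself, since the interval reaches up to 1.52 and 18 and 14 fragments are too few. Whether fragments of the overlapping NCAPD3 gene are among the 18 and 14 was not tested, so a knockdown hidden by them stays open.

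The genes at the ends of the ranking, SMN1 and HIST2H2AA4, each have a near-identical copy. A different split of the same fragments between copies is argued against, since the summed fragments of SMN1 and SMN2 still gave a log2 ratio of 2.48 (2.26 to 2.70) and those of HIST2H2AA4 and HIST2H2AA3 gave -4.58 (-5.73 to -3.62). For EIF3CL the sum with EIF3C gave -0.84 (-0.99 to -0.70) as the log2 of a ratio of 0.558, against a ratio of 0.0783 for EIF3CL alone, and EIF3C alone was higher in shJAM3 (ratio 1.54), so a split may account for part of it and the rest stays open. Multi-mapping fragments that the counting dropped are not in these sums, so unequal loss of them stays possible for all 3 pairs.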
